A study of Homo sapiens with 4 samples.

How the data were processed

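Total RNA was measured on 4 one-colour expression arrays, 2 of control cells and 2 of cells given berberine, a plant alkaloid. The labels name the cells as HepG2, a human hepatocellular carcinoma line. Per the labels' protocols, the treatment was 26.95 µM for 24 hours, RNA was extracted with a column kit, and Cy5-labelled amplified RNA was used. The samples' description field instead names a differentiation protocol of 48 hours, with 13.47 µM berberine in the treated samples. Because of that field, RNA of mouse adipocytes is weighed in the closing observations. The title, source and treatment fields and the series design text were followed here, and this conflict was not resolved. Replicate numbers were taken from the titles. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

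The deposited table holds intensity values on a linear scale, as whole numbers, for 26423 probes. The scanner, background method, normalization and software are not given in the sources used here. Values below 0 occurred in control 2 (269 probes), berberine 1 (1) and berberine 2 (11), as background subtraction would give. The sample medians were 90 and 62 in controls 1 and 2 and 77 and 85 in berberine 1 and 2. The 5th percentile was 4 in control 2 and 25 to 30 in the other samples. The deposited columns therefore did not share 1 distribution. The number of arrays limits the precision.

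All 26423 probe identifiers carry the prefixes of a mouse array. The platform annotation supplied for them names 543 probes as OLFR (mouse olfactory receptor) genes and 1663 as RIK (mouse clone) genes, while the labels give human cells. A value under a gene name is therefore the signal of a mouse probe and no direct measure of the human transcript. The annotation gave 20377 probes 1 gene symbol and 0 probes several. The other 6046 probes are unnamed here and were left out of the main test. Of the 17778 gene names, 12842 equalled a current human symbol, 1145 an older one, and 3791 had no human match. No detection call was used here. The 528 olfactory receptor genes served as a background reference, chosen after the data were seen. Their median level was 6.05 and their 95th percentile 9.24 on the log2 scale, and 1626 genes had means above that percentile.

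On the log2 scale the medians as deposited spanned 0.53, more than the 0.2 allowed by the planned rule, so intensities were quantile normalized, values under 0 were set to 0, and log2(value + 1) was taken. The plan did not foresee values below 0, and the floor was added for them. Fold changes are on the log2(value + 1) scale, where the added 1 matters only for values near 0. Those of dim genes are imprecise. In the dimmest of 10 equal groups by signal, the median absolute log2 fold change was 0.283 and the median replicate SD 0.344. A gene with several probes (2252 genes) was represented by the probe with the highest mean over the 4 samples. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes without a trend, all 4 samples, no block), 2-sided, with Benjamini-Hochberg adjustment over 17778 genes and a threshold of 0.05. The residual degrees of freedom were 2. An exact permutation test of a single value in this design cannot go below 0.333. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

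The tests, the other settings called planned, 34 gene lists (5 of them markers of other cell types) and the rule for named genes were fixed before the data were examined. Older symbols in the lists were matched where they belonged to 1 human gene. The 33 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, 2-sided, adjusted over the lists. The rule took the 6 largest rises and 6 largest falls among genes past the threshold with groups apart and a mean above the median gene, up to 2 members past the threshold of each list or otherwise the 1 with the smallest p, and a few fixed genes, among them CYP1A1, DDIT3, CDKN1A and ALB. The other fixed genes are not reported here. Fewer than 12 genes passed the threshold, so its first part took the smallest p-values in place of the threshold, as the rule provided. CYP1A1 was not analysed here. Another 30 genes are named outside the rule, after their values were seen. They are JUN, JUNB, IER3, KLF6, VLDLR, ATF4, GADD45A, ADM, TGFB1, FOXA1, RBP4, FABP4, RETN, AFP, ACTB and the genes of the closing observations.

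The settings fixed beforehand for comparison were the values as deposited, median centring, a filter on the dimmest 30% of genes, a pseudocount of 50, eBayes with an intensity trend or the robust option, the mean of a gene's probes, each probe as its own row, a minimum log2 fold change of 1, the replicate number as a block, each sample left out, camera with an estimated correlation, and fry. The fit with an intensity trend is called the trend test. It was one of these settings, and it was given room beside the main test after both counts had been seen. After the planned settings had been run, 3 kinds of fit were added: only genes above the olfactory receptor 95th percentile, the trend test with the block, and the trend test with a sample left out. Where a sample is left out, the lone sample of its group is assumed to vary like the other group.

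Both tests were tried on simulated data with the real means and 200 changed genes among 17778, drawn from genes above the median level, in 10 draws. The simulated spread came from the trended fit to these samples, which favours the trend test by construction. A first version had assumed 4.5 prior degrees of freedom, and it was replaced because those estimated from the samples were lower, 2.03 without and 2.81 with the trend. For the comparison of berberine with control, the main test recovered 1.19%, 77.8% and 91.8% of genes changed by 1, 2 and 3 on the log2 scale, and the trend test 46.4%, 89.6% and 96.1%. False calls made up 4.62% and 4.63% of all calls. In the first version the main test had recovered 3.13%, 81.6% and 96.5% and the trend test 13.1%, 88.5% and 98.0%, so the recovery of genes changed by 1 depends on the assumed spread.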

Results

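The series concerned berberine and the viability of HepG2 hepatocellular carcinoma cells. Expression was profiled on 4 arrays, from 2 control samples and 2 samples treated with 26.95 µM berberine for 24 hours. The table covered 26423 probes, with a median intensity of 62 to 90 per sample. The probes are those of a mouse array, so each gene name below is the name of the mouse probe that gave the signal. Over 17778 genes, Pearson's r across genes was 0.965 between the controls and 0.973 between the berberine samples, and 0.957 to 0.966 between samples of different groups. Genes are not independent replicates, and the mean r within groups exceeded that between groups by 0.0091.

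Probes named for the same gene were compared to see how far the names can be read. Over all 2252 genes with several probes, the log2 fold changes of 2 probes correlated at r = 0.053 across genes, with the same sign in 52.6%. Over the 82 genes whose probes both had means above 8 the values were 0.381 and 62.2%, and over the 21 genes with both above the olfactory receptor 95th percentile it was 0.550, with the same sign in 81.0%. Of all genes, 1626 had a mean above that percentile.

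**Figure D1:**
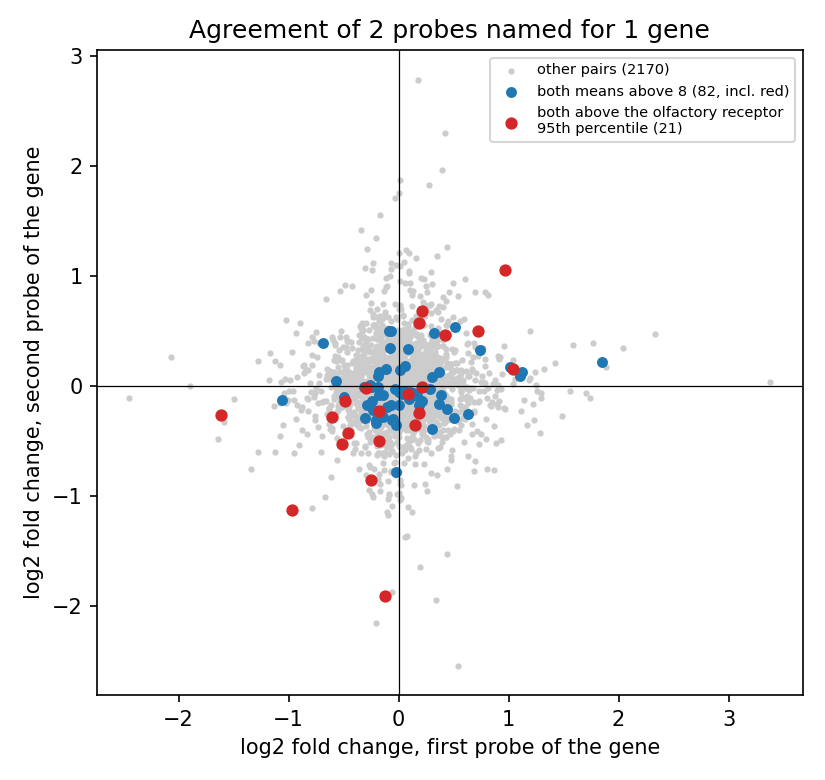
Log2 fold change (berberine minus control) of the first against the second probe named for the same gene, 1 point per gene. Blue and red points together are the 82 genes with both means above 8 (r = 0.381), red points the 21 with both above the olfactory receptor 95th percentile (r = 0.550), and gray points the rest.

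Berberine-treated and control cells were compared gene by gene. EGR1, an immediate early transcription factor, rose 23.6-fold, from 9.39 ± 0.12 to 13.95 ± 0.03 on the log2 scale (SD, n = 2 in each group). RN7SK, the small nuclear RNA that holds the elongation factor P-TEFb inactive, rose 16.0-fold, and RNU2, named for the U2 RNA of the spliceosome, rose 11.1-fold. BTG1, an antiproliferative gene, rose 10.4-fold. HIVEP2, a zinc finger transcription factor, rose 6.76-fold, and BHLHE40, a transcriptional repressor of the circadian clock, rose 6.51-fold. JAG1, a Notch ligand, rose 5.56-fold, and FOS, a partner of JUN in the AP-1 factor, rose 5.26-fold. MAGED1, of the melanoma antigen family, was the 1 gene that fell in this test, 6.05-fold, from 13.71 ± 0.10 to 11.11 ± 0.05 (SD, n = 2 in each group).

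**Figure D2:**
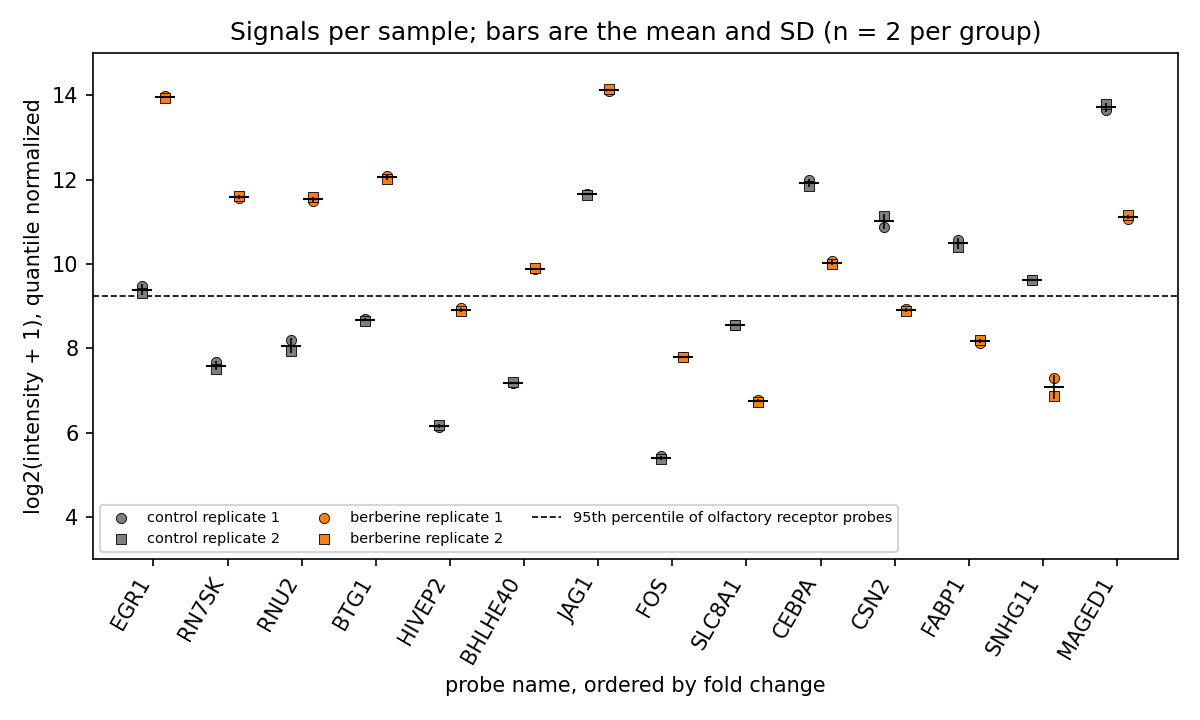
Quantile-normalized log2(intensity + 1) of each sample for the 9 genes past the threshold and 5 falling genes named by the rule, ordered by fold change, with group means and SDs (n = 2). Both berberine points lie on one side of both control points for each gene, which the rule required of the 5 falling genes. EGR1 moves from 9.39 to 13.95.

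These 9 genes (8 higher, 1 lower) had limma adjusted p-values from 0.0354 to 0.0474, with SEs of the log2 fold change up to 0.139. Both berberine values lay on one side of both controls, which folds this large with SEs this small already imply. At an unadjusted p under 0.05 there were 2318 genes, 1188 higher and 1130 lower, where chance gives about 889. The groups did not overlap for 45.0% of genes, where chance gives 33.3%. Shares for the other splits of the samples into equal groups are not given here. Pearson's r was 0.957 to 0.966 between samples of different groups, 0.965 between the controls and 0.973 between the berberine samples. The 45.0% and the 2318 genes therefore cannot be assigned to berberine rather than to other differences between arrays. BTG1 had a second, dim probe, at a level of 6.50, which differed by 0.04. HIVEP2, BHLHE40 and FOS had means below 9.24, the 95th percentile of the olfactory receptor genes. The control means of RN7SK (7.59), RNU2 (8.06), BTG1 (8.67), HIVEP2 (6.16), BHLHE40 (7.18) and FOS (5.41) also lay below it, so their folds are set against control signals in the background range. For HIVEP2 (8.91) and FOS (7.80) the berberine means lay in that range too. The count was 2, both higher, for values as deposited, and 0 after median centring or with each probe as its own row, where 2247 genes and 3101 probes had an unadjusted limma p under 0.05. It was also 0 without control 1, control 2, berberine 1 or berberine 2, with 1983, 2763, 1312 and 1370 genes at an unadjusted limma p under 0.05. The trend test without these samples, chosen after seeing the data, gave 0 as well, with 2222, 3098, 1380 and 1391.

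The spread between replicates depended on signal. With genes in 10 equal groups by signal, the median replicate SD was 0.344 on the log2 scale in the dimmest group and 0.080 in the brightest. With an intensity trend in limma's variance model, an alternative fixed beforehand, 260 genes passed, 171 higher and 89 lower, among them the 9 genes above. Of these 260, 142 lay in the brightest group and 134 above the olfactory receptor 95th percentile, 114 were at least 2-fold higher and 64 at least 2-fold lower. Of the 528 olfactory receptor genes, 2 passed the trend test and 0 the main test.

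**Figure D3:**
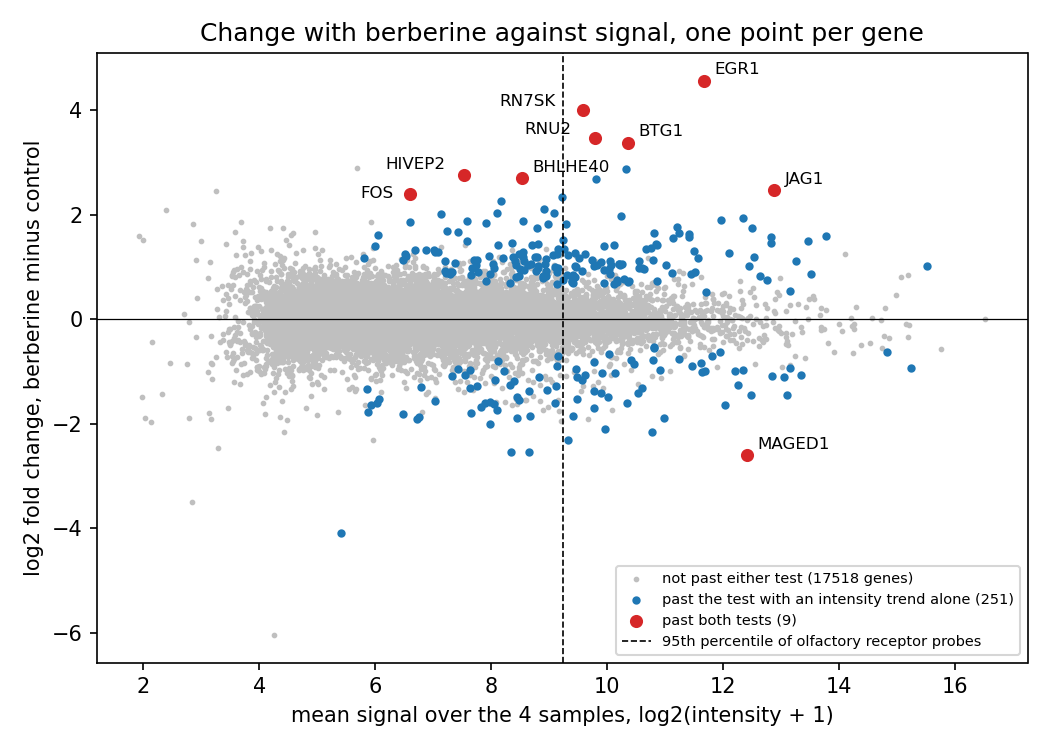
Log2 fold change (berberine minus control) against mean log2(intensity + 1) over the 4 samples for the 17778 genes. The 9 genes past both tests are red and named, the genes past the trend test alone are blue, and the dashed line marks the olfactory receptor 95th percentile at 9.24.

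Several other falling genes named by the rule passed the trend test and not the main test. FABP1, the fatty acid binding protein of liver, had a log2 fold change of -2.32 (limma trend adjusted p = 0.00489, main 0.0688). CEBPA, a hepatocyte transcription factor, was at -1.89 (limma trend adjusted p = 0.00489), the sodium-calcium exchanger SLC8A1 at -1.79 (0.00608), CSN2, named for the milk protein beta-casein, at -2.10 (0.00593), and the non-coding RNA SNHG11 at -2.54 (0.0083). SLC8A1 and SNHG11 had means below 9.24, and the berberine means of FABP1 (8.17), CSN2 (8.91), SLC8A1 (6.76) and SNHG11 (7.08) lay in that background range.

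Immediate early genes were the 1 list of 33 past the threshold in the camera test at its preset correlation, upward (adjusted p = 0.00656). With an estimated correlation the call was lost (camera adjusted p = 0.879). The list's unadjusted camera p was 0.000199 with the preset and 0.202 with the estimate. That estimate rests on 2 residual degrees of freedom, and the preset is an assumption, so the call depends on the correlation used. Of 19 measured members, EGR1 and FOS rose and 17 did not pass the main test. Adjusted over the list alone, 5 rose, the others being JUNB at 1.21, IER3 at 1.66 and KLF6 at 0.99, and JUNB and IER3 also passed the trend test. The second JUNB probe was at 0.10, and JUNB, IER3 and KLF6 had means below 9.24. JUN was at 0.02 (limma adjusted p = 0.975), and at -0.24 with values as deposited and -0.35 with median centring. The list's median log2 fold change was 0.21. The adjusted p was 0.0777 with fry, which tests a list against no change and not against the other genes. With camera it was 0.489 over genes above the olfactory receptor 95th percentile. It was 0.301 without control 2, 0.0584 without berberine 2 and 0.324 with median centring, in a range of 0.00375 to 0.879 over the alternatives.

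In the integrated stress response list (30 measured, ATF4 targets), 0 members passed the main test and 3 rose when adjusted over the list alone and in the trend test. These were CEBPB, a transcription factor, at 1.58, VLDLR, a lipoprotein receptor, at 1.24, and ATF4 itself at 0.99, while a second VLDLR probe was at -0.29. VLDLR and ATF4 had means below 9.24. DDIT3, the CHOP transcription factor, was at 0.35 (limma adjusted p = 0.366), and the list's camera adjusted p was 0.209. Among 17 p53 targets, 0 passed the main test and 2 rose when adjusted over the list alone and in the trend test, PLK3 at 1.94 and GADD45A at 1.11, both known for roles in stress and the cell cycle. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, was at -0.66 with an SE of 0.366 (limma adjusted p = 0.524), and its control samples read 9.23 and 8.27. The p53 list's camera adjusted p was 0.636. Among 18 apoptosis regulators, 0 passed the main test and BCL2L11, which encodes the proapoptotic protein BIM, rose when adjusted over the list alone and in the trend test, at 1.00 with a mean of 9.10, below 9.24 (camera adjusted p = 0.827).

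Genes of secreted and inflammatory signals showed a similar picture, with 0 members past the main test in each list. In the NF-kB and inflammatory list (19 measured), CCL20, a chemokine, at 1.84 and IER3 at 1.66 rose when adjusted over the list alone and in the trend test (camera adjusted p = 0.32). In the hypoxia list (13 measured), the angiogenic factor VEGFA at 1.64 and ADM, a vasodilator peptide that went from 6.83 to 8.33, did so too. The hypoxia list's median was -0.086 (0.0087 as deposited, -0.105 with median centring), its mean 0.199 and its camera direction up (adjusted p = 0.827). In the list of matrix and mesenchymal transition genes (22 measured), the same held for TIMP1, an inhibitor of matrix proteases, at 1.61 and TGFB1 at 1.39 (camera adjusted p = 0.209). CCL20, IER3, ADM and TIMP1 had means below 9.24.

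Liver genes were compared as transcription factors and as secreted proteins. Among 18 liver transcription factors, 0 passed the main test, while CEBPA at -1.89 and FOXA1 at -0.89 fell and CEBPB at 1.58 rose when adjusted over the list alone and in the trend test (camera adjusted p = 0.827). Of 31 secreted liver proteins 0 passed the main test, and FGG, the fibrinogen gamma chain, at -1.77 and RBP4, the retinol carrier of plasma, at -1.08 fell when adjusted over the list alone and in the trend test. The 2 dimmer RBP4 probes were at -0.15 and -0.22, and FGG, with a mean of 5.88, and FOXA1, with a mean of 9.14, lay below 9.24. ALB, albumin, was at -0.41 with an SE of 0.129 (limma adjusted p = 0.35). The list's median was 0.059, its mean -0.013 and its camera direction up (adjusted p = 0.854), and the direction turned down with values as deposited and with median centring. Of these 31 genes 4 had means above 9.24, and the probe named AFP, a fetal plasma protein that HepG2 cells are known to secrete, read 4.75. In the acute phase list (15 measured, 0 past the main test), FGG was the 1 member that fell when adjusted over the list alone and in the trend test (camera adjusted p = 0.531).

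Lipid and glucose metabolism, for which berberine is widely studied, had 0 genes past the main test in each list. Of 19 genes of fatty acid and triglyceride synthesis, DGAT1, which makes triglyceride, fell when adjusted over the list alone and in the trend test, at -1.17 with a mean of 8.07, below 9.24 (camera adjusted p = 0.636). Of 19 genes of fatty acid oxidation and ketone synthesis, FABP1 did (camera adjusted p = 0.304). Of 18 genes of the cholesterol synthesis list, 0 passed the trend test or the list-alone adjustment, and TM7SF2, a sterol reductase, was at -0.42 (limma adjusted p = 0.333, camera adjusted p = 0.678). None of these 18 had a mean above 9.24. Of 15 genes of glycolysis and glucose uptake and 12 of gluconeogenesis and glycogen, 0 passed either adjustment. The hexokinase HK1 was at 0.66, with a second probe at -0.34, and PPP1R3C at 0.28, and the camera adjusted p-values were 0.465 and 0.745. Of 35 nuclear genes of oxidative phosphorylation 0 passed, and NDUFS4, a subunit of complex I, was at 0.63 with a second probe at -0.20 (camera adjusted p = 0.827). Of 10 bile acid genes 0 passed, and OSTA, a bile acid transporter, was at 0.46 (camera adjusted p = 0.827).

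Growth genes had 0 members past the main test in each list. Of 24 genes of S phase and DNA replication, E2F1, a transcription factor of S phase entry, fell when adjusted over the list alone and in the trend test, at -1.42. Of 25 genes of G2 and mitosis 0 passed, and the kinase BUB1 was at -0.70 with a second probe at 0.15. The camera adjusted p was 0.827 for both lists. Nucleotide synthesis (15 measured, PRPS1 at -0.68) and ribosome biogenesis (16 measured, NCL at -0.55 with a second probe at -0.11) had 0 members past the trend test, with camera adjusted p-values of 0.636 and 0.827. The median of the ribosome biogenesis list was -0.021, its mean 0.014 and its camera direction down. The median turned to 0.165 with values as deposited and 0.051 with median centring, with the camera direction up.

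Among drug and stress responses, 0 members passed the main test in each list. ABCC2, an exporter of conjugated drugs, rose when adjusted over the list alone and in the trend test, at 1.34, in both the xenobiotic (11 measured) and the NRF2 (20 measured) list, with camera adjusted p-values of 0.209 and 0.827. ABCC2 had a mean of 9.15, below 9.24. The NRF2 list's median was -0.127 (0.107 as deposited, -0.0061 with median centring), its mean 0.079 and its camera direction up. In the unfolded protein response list (18 measured), DNAJB11, a chaperone, rose when adjusted over the list alone, at 1.02 with a mean of 7.45, below 9.24, and other probes at 0.23 and -0.30. That list's median was -0.031, its mean 0.078 and its camera direction down (adjusted p = 0.98). Its median turned to 0.210 with values as deposited and 0.097 with median centring, with the camera direction up. For 10 heat shock, 21 autophagy and lysosome, 14 interferon and 6 histone genes, 0 passed the trend test, and the smallest p-values belonged to HSPE1 at 1.12, ATP6V1H at 0.60, USP18 at 0.36 and HIST1H1C at 0.70. Their camera adjusted p-values were 0.636, 0.685, 0.827 and 0.827. Of the metallothionein list 1 gene was measured, the zinc exporter SLC30A1, at 0.64, and the list was not tested.

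Markers of other cell types passed the main test in 0 cases. Among 18 adipocyte markers, CEBPA, which hepatocytes also express, and RETN at -1.20 fell and FABP4 at 1.00 rose when adjusted over the list alone, and CEBPA passed the trend test (camera adjusted p = 0.465). Their median level was 6.58, against 6.54 for all genes. Of 11 fibroblast markers POSTN at 0.96 rose, and of 8 lymphocyte markers CD2 at -0.65 fell, when adjusted over the list alone, and neither passed the trend test. RETN, FABP4, POSTN and CD2 had means below 9.24. Of 11 macrophage and 10 endothelial markers 0 passed, with CD14 at 0.40 and CDH5 at -0.25. The camera adjusted p-values were 0.827 for fibroblast, macrophage and endothelial markers and 0.636 for lymphocyte markers.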

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

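Of the tests below, the one of short non-coding RNAs was set out before its result was seen, and the tests of probe names, adipocyte markers, ribosomal protein genes and the immediate early list were chosen only after. Unnamed probes were left out of the main comparison, and 342 of 6046 had means above the olfactory receptor 95th percentile. With every probe as its own row in the trend test, 20 of the 6046 unnamed probes were higher with berberine than in the control samples and 15 were lower, while without the trend 0 passed. In the trend test per gene, 2 of 528 olfactory receptor genes passed, and whether the unnamed probes exceed that rate was not tested. The largest rise was 2.12 on the log2 scale, for PH_mM_0005487, from 7.86 to 9.98, and the largest fall was -1.78, for PH_mM_0014102, from 8.73 to 6.95. Means of these probes over all samples, 8.92 and 7.84, lay below the olfactory receptor 95th percentile. Of the 35 probes that passed, some lay below it and others above. Those above included mMC019764 (2.01, mean 9.92), PH_mM_0017629 (1.54, mean 14.76) and, lower with berberine, PH_mM_0015658 (-1.73, mean 13.39).

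A pattern that bears on every gene name is that mouse probes reported on samples labelled as human cells. Rows wholly out of register with their names are argued against by same-gene probe pairs with both means above 8, whose fold changes correlated at 0.381 across genes, against 0.171 for the 95th percentile of 1000 shuffled pairings. RNA of mouse adipocytes was named for the description field. The 18 adipocyte markers had a median level of 6.58, but 33 ribosomal protein genes, abundant in any cell, had one of 6.83. A low marker level therefore excludes no cell type. Mouse RNA on matched mouse probes predicts bright ribosomal protein genes, and 3 of the 33 exceeded the olfactory receptor 95th percentile. Those 33 genes were dimmer than this prediction. Rows partly out of register with their names were not tested and could scatter them too. Mouse RNA, of adipocytes or other cells, was therefore not excluded. Human RNA on mouse probes, with signal set by sequence match, stays open. The ribosomal protein genes lay at a median percentile of 57.1 among all genes, and levels of same-gene pairs correlated at 0.076 over all 2252 pairs but at 0.444 over the 82 above 8 and 0.649 over the 21 above the olfactory receptor 95th percentile.

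A second pattern is the rise of EGR1, FOS, RN7SK and RNU2. A higher share of short non-coding RNA in the labelled RNA, which predicts nothing for the messenger RNAs EGR1 and FOS, stays open for RN7SK and RNU2. The median log2 fold change of 13 other such genes was -0.049 (bootstrap SE 0.084), which met the bound set beforehand against it. That bound did not ask for signal: 0 of the 13 had a mean above the olfactory receptor 95th percentile. The control means of RN7SK (7.59) and RNU2 (8.06) lay below it too, so that mark cannot tell which probes respond. The brightest of the 13 were SCARNA6 (mean 8.32) at 0.48, RNU11 (7.68) at 0.14 and RNU7 (7.57) at -0.01. Whether their probes respond is not known, so these values were not taken to exclude the explanation. For EGR1 and FOS, a joint early response to berberine, the biological explanation, stays open too. The median of the immediate early list without them was 0.056, with bootstrap bounds of -0.024 and 0.307. That shortened list had a camera p of 0.0153 (adjusted 0.209). Genes are not independent replicates, so neither these bounds nor the bootstrap SE above measures the spread between samples.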

How the results depend on the processing

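Tests restricted to genes above the olfactory receptor 95th percentile, the trend test with the block and the trend test without a sample were chosen only after the data were seen. For the 45 genes named by the rule or past the threshold, 438 results kept their direction and side of the threshold over the alternatives, 53 gained and 62 lost significance, and 0 reversed. Only the 9 genes past the main test could lose significance, so the 62 losses were all theirs. For the other genes, a kept result means that they stayed short of the threshold. The 9 changed genes stayed at 9 with robust moderation and a minimum log2 fold change of 1, and 8 of them passed with the mean of all probes. The count was 2 for values as deposited, 0 after median centring, 0 with each probe as its own row, 138 (92 higher) without the dimmest 30%, 251 (166 higher) with a pseudocount of 50 and 260 (171 higher) with the trend. The last 3 settings each included all 9 genes, the 138 were all among the 260, and 247 were shared by the pseudocount and trend settings. Above the olfactory receptor percentile 434 of 1626 genes passed, 217 each way, among them 6 of the 9. Without a sample the count was 0 to 0, with or without the trend. With the replicate number as a block it was 0 (1878 at an unadjusted limma p under 0.05), and 202 (122 higher) with trend and block. The labels give the samples only a shared number, and 2 pairs cannot settle whether it marks a pairing. Deviations of same-numbered samples correlated at 0.09 over all genes and 0.332 above the olfactory receptor percentile. The 1 list past the threshold became 2 without the dimmest 30% (matrix genes joined), 0 after median centring, 0 above the olfactory receptor percentile (3 lists tested), 0 with an estimated correlation, 0 with fry (12 at an unadjusted p under 0.05), and 0 to 1 without a sample. Robust moderation was not run for lists. The excess of r within groups went from 0.0091 to 0.0153 without the dimmest 30% and 0.080 above the olfactory receptor percentile. The cause of these differences was not tested. Signal over background limits most genes, since 1626 of 17778 exceeded that percentile.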

Other observations

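Genes outside the lists also passed the trend test. Those named here were chosen only after their values were seen, and no theme was tested for enrichment. Among the higher genes were LIF, a cytokine of the interleukin-6 family, at 2.88 on the log2 scale, VGF, a neuropeptide precursor, at 2.68, the chromatin remodeller CHD2 at 1.97, the transcription factor FOXP1 at 1.91 and IFRD1 at 1.82. ZFP36L1, which promotes decay of AU-rich transcripts, was at 1.59, from 12.99 to 14.58. The other CHD2 probes, both dim, were at 0.90 and -0.18. These 6 genes had means over the 4 samples above the olfactory receptor 95th percentile, as had the lower genes that follow, except KRT8. Such a mean can exceed it through the higher group alone.

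Among the lower genes were the endocytic receptor LRP1 at -1.64, the R-spondin receptor LGR4 at -1.61, the adhesion molecule CADM1 at -2.16 and the receptor kinase ERBB3 at -0.95. ABCA1, a cholesterol exporter, was at -0.84, LCAT, which esterifies cholesterol in plasma, at -0.79, and RAD54L, a recombination repair gene, at -1.41. The largest fall among genes past the trend test was KRT8 at -4.09, from 7.46 to 3.37, both below the olfactory receptor 95th percentile. CD36 was uneven between replicates, with SDs of 1.04 in the controls and 0.842 in the berberine samples (limma adjusted p = 0.794). ACTB, often used as a reference gene, was at 1.15 with a control SD of 0.826 (limma adjusted p = 0.387).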
